A study of Mus musculus with 6 samples.

How the data were processed

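Gene expression was measured in dendritic cells grown for 1 week from mouse bone marrow with GM-CSF, a growth factor. The cells took up ovalbumin coupled to a fluorescent dye and were parted by flow cytometry into mannose receptor (MR) negative and MR-positive cells. Per the labels, the sorted cells were lysed at once, RNA was cleaned on a column with a DNase step, and biotin-labelled cRNA was made for Illumina bead arrays. There were 3 arrays of each population, 6 in all. Their titles give the numbers M1 to M3, and the labels do not say whether these stand for mice, cultures or days. The description labels give a replicate number that is the same for all arrays of a population, so they were not used to tell arrays apart.

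The deposited non-normalized table gives for each of 45281 probes and each array an intensity on a linear scale. Its values ran from 16.8 to 26235 in arbitrary units, with array medians of 27.6 to 30.3, which shows that no background had been subtracted and no scaling between arrays applied. Per the file headers, each intensity comes with a p-value. These p-values fell as the intensity rose and were whole multiples of 1 in 936, so they were read as detection p against that number of negative control probes on the same array. A further deposited table holds intensity values that the authors had quantile normalized on a linear scale. Every array has the same sorted values there, within 0.071% of the mean of the sorted non-normalized signals, and each column has rank correlation 1 with its own array and at most 0.913 with another. The upstream software, scanner and any outlier removal are not given in the sources used here.

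The non-normalized intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc corrected the background with a normal-exponential model whose background was estimated from the detection p, quantile normalized the arrays, added an offset of 16 and took log2. A probe was kept when its detection p was under 0.05 on at least 3 of the 6 arrays, which left 16686 probes. The probe annotation gave a single gene symbol for 34885 of the 45281 probes and several symbols for 18, and 10378 were not listed there. Of those with a symbol, 34807 had a gene ID in the reference gene table, and no symbol needed updating. Probes without a single gene were tested but not named. No genome was used, so no coordinates are given. Of the tested probes, 14389 had a single gene, and the probe with the highest mean stood for each of the 9370 genes. Of 3474 genes with more than 1 tested probe, 2 had probes called in opposite directions.

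Differences are MR-positive minus MR-negative on the log2 scale, with the standard error of the fit. A linear model with the population as its single term was fitted with lmFit and eBayes of limma, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05. Gene counts and list counts use the 1 probe per gene. "Adjusted over the list alone" means the same p-values adjusted within a list. Gene lists were tested with camera of limma, with its preset correlation of 0.01 between genes, on 23 lists with at least 5 measured genes, adjusted over these lists. The adjusted p with a correlation estimated from the data is given beside it, and fry of limma was also run. With an estimated correlation camera takes its degrees of freedom from the arrays, not from the genes. With 6 arrays the same statistic then gives a larger p. That adjusted p therefore need not reflect a larger correlation: the lysosomal list did not pass there with an estimate of 0.0096. The 24 gene lists, the tests, the filters, the rule for naming genes and most of the alternatives were fixed before the data were examined. Of the list members, H2-L and BC100530 could not be matched to a gene.

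Named genes were Mrc1, Pparg and Cd274, then the 10 largest rises and the 10 largest falls among genes past the threshold whose populations do not overlap, and from each list up to 4 members with the largest absolute change among those past the threshold, or the 2 with the smallest p where none passed. Members outside this rule are named where 5 or fewer genes of a list moved one way, or where the text singles one out, and these were chosen after their values were seen. Where a gene was undetected on some or all arrays of a population, its fold is a lower bound: the mean of the other population was compared with, on each array of that one, the higher of the lowest level of a detected probe and the gene's own level.

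Whether the title numbers pair an MR-negative with an MR-positive array was checked by correlating, across probes, each array's deviation from the mean of its population. The correlation was 0.708 for the M1 arrays, 0.569 for M2 and 0.275 for M3. Arrays of M2 and M3 with unlike numbers were also positively related, at 0.290 and 0.382, both above the M3 pair. Deviations within a population cancel out, so with M1 apart the M2 and M3 arrays tend to correlate whatever their pairing. The check therefore relates the M1 arrays and leaves the pairing of M2 and of M3 undecided. A fit with the number as a block is given as an alternative beside the counts of the lists, except for the 2 lists (eosinophil, erythroid and megakaryocyte) where it gave the same counts. Log2 values correlated at 0.968 to 0.992 within MR-negative arrays, 0.977 to 0.992 within MR-positive arrays and 0.939 to 0.965 between the populations. No 2 arrays shared identical values.

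The precision of array values is set by the number of arrays and by the signal over background, and the median standard error of a log2 difference was 0.157. The procedure was tested on simulated data of the same layout, in which 82% of 100 planted 2-fold differences and 5.05% of 99 planted 1.5-fold differences were recovered. Differences were planted only in probes with a gene and a signal well above background, and the simulated spread between arrays was capped. These shares need not hold for dim or more variable probes. In that test 6 unchanged probes were called, 5.88% of the calls, and camera called the 1 shifted list and 0 of the 22 others. The simulated noise was independent between probes and held no difference between title numbers, so it cannot show how camera behaves with correlated genes. In the real data the estimated correlation reached 0.82 for the proliferation list, and other splits of the 6 arrays called up to 7 lists. The split with 7 put both M1 arrays on the same side, so its calls may reflect their difference and do not measure camera's errors. Numbers of detected probes were compared by a two-sided exact permutation test. Alternatives covered the background correction, the scaling between arrays, the authors' normalized values, the filter, the block, array weights, the variance model, the thresholds, the probe of a gene, the correlation between genes, and leaving out each array or each title number. Tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.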

Results

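Bone marrow cells of mice were cultured for 1 week with GM-CSF, a growth factor that drives them towards dendritic cells, and were then given fluorescent ovalbumin. Ovalbumin is a glycoprotein that the mannose receptor (MR) takes up, and its uptake was used to part MR-positive from MR-negative cells in a flow cytometric sort. Total RNA of the 2 populations was labelled and hybridised to Illumina bead arrays. There were 3 arrays of MR-negative and 3 of MR-positive cells, and the sample titles number the arrays of each population M1 to M3. Each array held 45281 probes, of which 15988 to 16641 (35.3% to 36.8%) were detected at a detection p under 0.05. The MR-negative arrays detected 16585 ± 70.9 probes (SD, n = 3) and the MR-positive arrays 16194 ± 357 (SD, n = 3). The difference of -390 probes did not pass a two-sided exact permutation test (p = 0.2, where 0.1 is the smallest p that 3 against 3 arrays allow). The number of arrays limits the precision of every value below. The labels do not say whether the arrays of a population came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

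The design holds 1 comparison, MR-positive against MR-negative dendritic cells, and the study's title places it in work on PPARγ activation, antigen cross-presentation and cross-priming. Mrc1, which encodes the receptor behind the sort, was 6.21-fold higher in MR-positive cells, with a log2 difference of 2.64 ± 0.39 (SE, adjusted p = 0.0051). Its mean normalized log2 intensity was 9.40 ± 0.69 (SD, n = 3) in MR-negative and 12.03 ± 0.56 (SD, n = 3) in MR-positive cells, and it was higher in 3 of 3 MR-positive arrays. This gene checks the sample labels and is no finding. Pparg, the gene of the nuclear receptor PPARγ, was 3.02-fold higher in MR-positive cells (log2 difference 1.60 ± 0.25, adjusted p = 0.0061), while a second, dimmer Pparg probe differed by 0.58 ± 0.17 and did not pass (adjusted p = 0.067). Cd274, which encodes the inhibitory ligand PD-L1, was 1.99-fold higher (0.99 ± 0.19, adjusted p = 0.0155). Without the MR-positive array of M2 or that of M3, the adjusted p of Cd274 was 0.067 and 0.064.

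**Figure D1:**
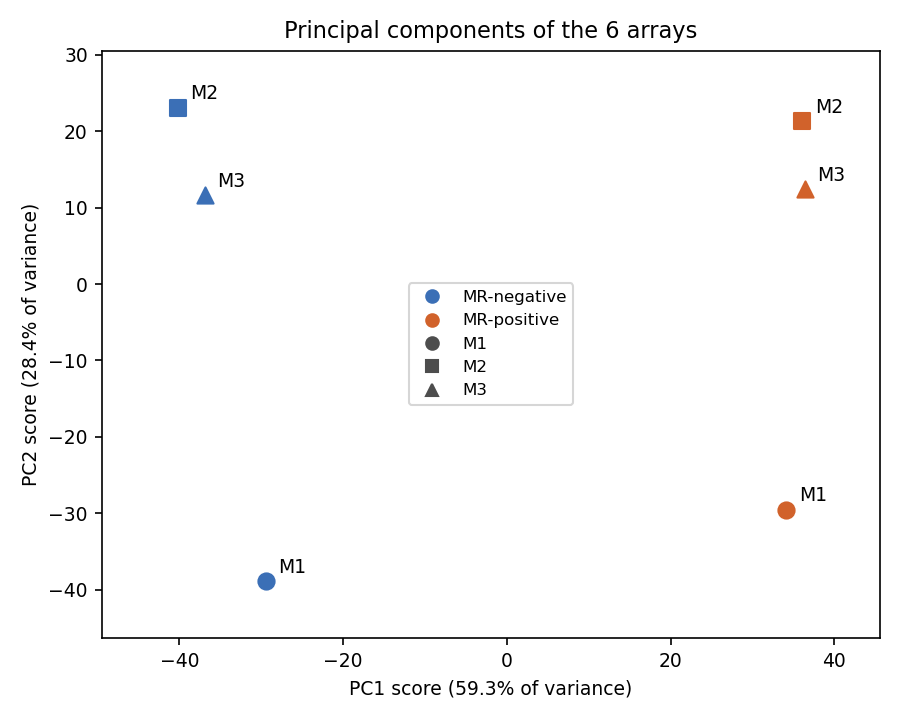
Scores of the 6 arrays on the first and second principal components of the normalized log2 intensities, coloured by population and marked by title number. The first component (59.3% of the variance) parted MR-negative arrays (-40.2 to -29.5) from MR-positive arrays (34.1 to 36.4), and the second (28.4%) set both M1 arrays (-38.8 and -29.5) apart from the other 4.

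Of the 9370 named genes measured, 767 were higher and 668 lower in MR-positive cells at an adjusted p under 0.05, and 279 of the higher and 314 of the lower ones differed at least 2-fold. Over all 16686 probes tested, 2298 (13.8%) passed, 1200 higher and 1098 lower, and 910 of them differed at least 2-fold. With the title number as a block, 1535 genes were higher and 1275 lower, and 4628 probes passed, all 2298 of the unblocked fit among them. The MR-negative and MR-positive values did not overlap for 32.8% of the tested probes, where chance gives 10%. When arrays were scaled to equal medians only, 30.6% of the calls were higher in MR-positive cells instead of 52.2%, and the median of all tested probes moved by -0.11 in log2 against 0.02. The count of probes fell to 1355 without the MR-negative array of M2, 1172 without the MR-positive array of M2, 1151 without the MR-negative array of M3 and 1159 without the MR-positive array of M3.

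The largest rise in MR-positive cells was that of Mmp13, a collagenase (log2 difference 4.32 ± 0.17, adjusted p = 5.1e-05), and Mmp14, a membrane-bound matrix metalloproteinase, was 7.36-fold higher (2.88 ± 0.25, adjusted p = 5.6e-04). Igf1, insulin-like growth factor 1, was 11.8-fold higher (3.56 ± 0.17, adjusted p = 5.1e-05), and Cck, the precursor of the peptide hormone cholecystokinin, was at least 15.1-fold higher (adjusted p = 0.0015), with 2 of 3 MR-negative arrays detecting it. The other rises, each with an adjusted p under 0.05, were H2-M2, a non-classical MHC class I gene (log2 difference 3.33 ± 0.36), Fstl1, a secreted glycoprotein (9.37-fold), Gstm2, a glutathione transferase (8.84-fold), Plpp3, a lipid phosphate phosphatase (7.08-fold), the orphan receptor gene Gprc5b (6.51-fold) and the DNA helicase gene Zranb3 (6.43-fold). Plpp3 no longer passed without the MR-negative array of M2 (adjusted p = 0.062), the MR-positive array of M2 (0.084), the MR-negative array of M3 (0.060) or the MR-positive array of M3 (0.067), and Zranb3 no longer passed without the MR-negative array of M3 (0.066). Mmp13 had 3 tested probes, and their log2 differences ranged from 0.65 to 4.32, all past the threshold. A second, dimmer Plpp3 probe differed by 0.61 ± 0.21 and did not pass (adjusted p = 0.11). A dimmer Gprc5b probe passed but differed by only 0.98 ± 0.15 (adjusted p = 0.0054).

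The 10 largest falls included genes of lymphocyte receptors. Cd3g, which encodes a chain of the T cell receptor complex, was 63.0-fold lower in MR-positive cells (log2 difference -5.98 ± 0.30, adjusted p = 6.4e-05), with a mean log2 intensity of 11.17 ± 0.56 (SD, n = 3) in MR-negative cells and 5.19 ± 0.38 (SD, n = 3) in MR-positive cells. Cd3d, another chain of that complex, was detected on no MR-positive array and was at least 13.7-fold lower (adjusted p = 9.2e-04). Klrd1, the NK cell receptor subunit CD94, was at least 22.4-fold lower (adjusted p = 0.0024), and Cd6, a lymphocyte surface receptor, was 17.2-fold lower (-4.11 ± 0.28, adjusted p = 2.4e-04). Scin and Avil, which encode actin-severing proteins of the gelsolin family, were 34.4-fold and at least 24.9-fold lower. Asb2, a ubiquitin ligase subunit, was at least 23.1-fold lower, and the scaffold protein gene Grasp at least 17.6-fold lower. Adam23, a membrane protein of the disintegrin family, was at least 22.3-fold lower, and Itgae, the integrin chain CD103, at least 14.7-fold lower. Each of these genes had an adjusted p under 0.05 by the probe that stood for it. A second, dimmer Grasp probe differed by -0.95 ± 0.39 and did not pass (adjusted p = 0.17). The dimmer Itgae probes all passed but differed by as little as -1.58 ± 0.14 (adjusted p = 5.5e-04). Of the MR-positive arrays, 2 of 3 detected Avil, Asb2, Klrd1 and Adam23, and 1 of 3 detected Grasp and Itgae.

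**Figure D2:**
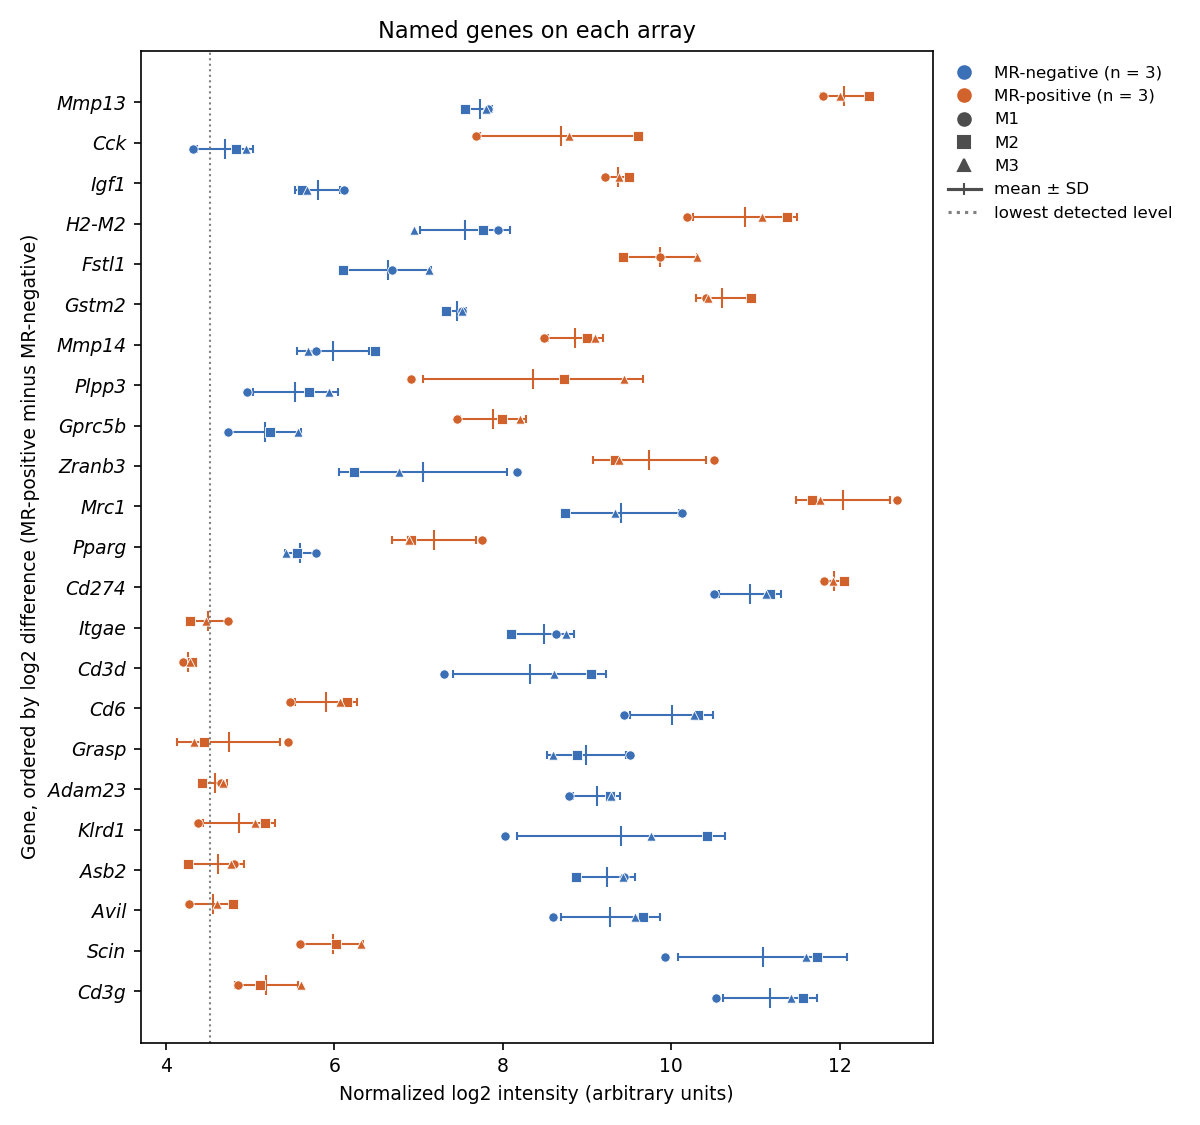
Normalized log2 intensity (arbitrary units) of Mrc1, Pparg, Cd274 and the 10 genes with the largest rise and the 10 with the largest fall, ordered by the difference between the populations, with a point per array, a tick at the mean and a bar for the SD (n = 3). The dotted line is the mean over arrays of the lowest level of a detected probe. The 3 MR-positive values lie apart from the 3 MR-negative values for every gene shown.

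Genes of dendritic cell maturation and costimulation were lower in MR-positive cells. Of 37 measured genes, 18 fell, 1 rose and 18 did not pass, and 21 fell and 1 rose when adjusted over the list alone, and 23 fell and 2 rose with the block. The list's median log2 difference was -0.90 (camera adjusted p = 1.4e-09, and adjusted p = 0.13 with an estimated correlation). The deepest falls were in Il4i1, a secreted amino acid oxidase (-3.99 ± 0.19, adjusted p = 5.7e-05), Fscn1, the actin-bundling protein fascin of mature dendritic cells (detected on 2 of 3 MR-positive arrays and at least 12.7-fold lower, adjusted p = 1.4e-04), Stat4, a signal transducer of cytokine receptors (-3.59 ± 0.30, adjusted p = 5.0e-04), and Serpinb6b, a serine protease inhibitor (-3.29 ± 0.19, adjusted p = 1.3e-04). Ccr7, the chemokine receptor that guides dendritic cells to lymph nodes, fell by 3.23 ± 0.28 (adjusted p = 5.6e-04). Cd274 was the gene that rose. The costimulatory ligand genes Cd80 (-0.08 ± 0.22, adjusted p = 0.86) and Cd86 (-1.26 ± 0.36, adjusted p = 0.060) did not pass, and both were singled out after their values were seen. Without the MR-positive array of M3, 12 genes of this list fell and 0 rose.

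Genes of MHC class II presentation were also lower, with 10 of 15 measured genes falling, 3 rising and 2 not passing, with 11 falling and 3 rising when adjusted over the list alone, and likewise 11 and 3 with the block. The median log2 difference was -0.67 (camera adjusted p = 2.3e-04, and adjusted p = 0.13 with an estimated correlation). H2-Oa, a chain of the peptide-loading regulator H2-O, fell by 2.65 ± 0.18 (adjusted p = 2.4e-04), Ciita, the transactivator of class II genes, fell by 2.34 ± 0.38 (adjusted p = 0.0073), H2-Eb2, a class II beta chain gene, fell by 1.97 ± 0.19 (adjusted p = 9.2e-04), and H2-Ob, the partner chain of H2-Oa, fell by 1.80 ± 0.21 (adjusted p = 0.0018). The dimmer H2-Eb2 probes differed by -2.93 ± 0.31 (adjusted p = 0.0012) and by -0.47 ± 0.13 (adjusted p = 0.056, not past the threshold). The 3 genes that rose were Ctss (1.00 ± 0.22, adjusted p = 0.023) and Lgmn (0.74 ± 0.13, adjusted p = 0.011), which encode lysosomal proteases, and Marchf1 (0.72 ± 0.17, adjusted p = 0.030), a ubiquitin ligase that acts on MHC class II molecules. Genes of MHC class I and cross-presentation did not pass as a list, and their calls depended on the scaling. Of 31 measured, 3 rose, 5 fell and 23 did not pass, with 4 and 7 when adjusted over the list alone (median log2 difference -0.10, camera adjusted p = 0.55). H2-D1, a classical class I heavy chain, rose by 0.99 ± 0.16 (adjusted p = 0.0065), as did the NADPH oxidase gene Cyba (0.64 ± 0.12) and the non-classical class I gene H2-M3 (0.57 ± 0.11). Of the dimmer H2-D1 probes, that at 0.88 ± 0.20 passed (adjusted p = 0.026) and that at 0.86 ± 0.28 did not (adjusted p = 0.091). Rab27a, a small GTPase of vesicle transport, fell by 1.92 ± 0.17 (adjusted p = 6.6e-04), the translocon gene Sec61b fell by 0.90 ± 0.13 (adjusted p = 0.0043), and the proteasome genes Psmb9 (-0.67 ± 0.15), Psme1 (-0.57 ± 0.13) and Psmb8 (-0.45 ± 0.11) fell with adjusted p from 0.027 to 0.040. With the block, 8 class I genes rose and 8 fell, while with equal medians 0 rose by limma and 8 fell, and H2-D1 differed by 0.63 and did not pass (adjusted p = 0.055). Without the MR-positive array of M2, 8 class II genes fell and 0 rose. Leaving out either M2 array, or the MR-negative array of M3, left 4 class I genes called, leaving out the MR-positive array of M3 left 3, and Psmb9 passed under none of these 4 (adjusted p 0.057, 0.095, 0.067 and 0.107 in the order MR-negative M2, MR-positive M2, MR-negative M3, MR-positive M3).

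Lysosomal and endosomal genes were higher in MR-positive cells. Of 36 measured, 18 rose, 0 fell and 18 did not pass by limma, where at an unadjusted p under 0.05 25 rose and 0 fell, and 23 rose when adjusted over the list alone. With the block, 24 lysosomal and endosomal genes rose and 0 fell. The median log2 difference was 0.67 (camera adjusted p = 1.9e-09, and adjusted p = 0.069 with an estimated correlation). The largest rises were in Ctsk, a cysteine protease (1.93 ± 0.25, adjusted p = 0.0030), Lipa, the lysosomal acid lipase (1.88 ± 0.26, adjusted p = 0.0037), Igf2r, the mannose-6-phosphate receptor that delivers enzymes to lysosomes (1.67 ± 0.17, adjusted p = 0.0010), and Ctsa, a lysosomal carboxypeptidase (1.24 ± 0.12, adjusted p = 7.7e-04). Of the dimmer Ctsa probes, those at 0.53 ± 0.23 and 0.81 ± 0.27 did not pass (adjusted p = 0.19 and 0.090), and the others did. Without the MR-negative array of M3, and without the MR-positive array of M3, 11 genes rose in each case.

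Uptake and scavenger receptor genes were higher as a list but moved both ways. Of 27 measured, 11 rose, 4 fell and 12 did not pass, 15 rose and 5 fell when adjusted over the list alone, and 15 rose and 7 fell with the block. The median log2 difference was 0.54, or 0.53 with genes undetected in a population set at their bound (camera adjusted p = 0.018, and adjusted p = 0.18 with an estimated correlation). Besides Mrc1, the low-affinity IgG receptor gene Fcgr4 rose by 1.86 ± 0.19 (adjusted p = 0.0012). Cd207, the C-type lectin langerin, was detected on no MR-positive array and was at least 6.26-fold lower (adjusted p = 5.1e-05), and Cd209c, a relative of DC-SIGN, fell by 1.67 ± 0.16 (adjusted p = 8.8e-04). The lectin genes Mgl2 (-0.71 ± 0.12, adjusted p = 0.0081) and Clec10a (-0.58 ± 0.15, adjusted p = 0.049) were the other 2 that fell. Without the MR-negative array of M1 the list did not pass (adjusted p = 0.067), nor without both M1 arrays (0.059), and without the MR-positive array of M3 6 genes rose and 3 fell.

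PPARγ targets and lipid handling genes did not pass as a list (median log2 difference 0.12, camera adjusted p = 0.15), although fry, which asks only whether genes move one way on balance, gave an adjusted p of 0.0034. Of 27 measured, 8 rose, 2 fell and 17 did not pass, with 9 and 3 when adjusted over the list alone, and with 11 and 6 with the block. Besides Lipa and Pparg, Nr1h3, the oxysterol receptor LXRα, was undetected on all MR-negative arrays and at least 2.97-fold higher (adjusted p = 2.8e-04), and Lpl, lipoprotein lipase, rose by 1.66 ± 0.45 (adjusted p = 0.049). The 2 that fell were Slc25a20, the mitochondrial carnitine carrier (-1.50 ± 0.28, adjusted p = 0.013), and Elovl5, a fatty acid elongase (-0.66 ± 0.16, adjusted p = 0.031). Of the single arrays, Lpl could lose only the MR-negative array of M1 and still pass, its adjusted p being 0.112 without the MR-positive array of M1, 0.114 and 0.124 without the MR-negative and MR-positive arrays of M2, and 0.161 and 0.129 without those of M3. It also did not pass with normexp at offset 50 (adjusted p = 0.061), cyclic loess (0.076) or equal medians (0.094). With equal medians 4 genes of the list rose and 2 fell. Leaving out either M2 array left 5 genes of the list called, and leaving out either M3 array left 4.

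Genes of alternative activation showed no common direction (median log2 difference 0.17, camera adjusted p = 0.92). Of 25 measured, 4 rose, 5 fell and 16 did not pass, with 4 and 7 when adjusted over the list alone, and with 9 and 9 with the block. Il1rn, the antagonist of the interleukin-1 receptor, rose by 2.16 ± 0.12 (adjusted p = 1.0e-04). The chemokine gene Ccl8 was undetected on all MR-negative arrays and at least 3.78-fold higher (adjusted p = 0.019), and Rnase2a rose by 1.18 ± 0.28 (adjusted p = 0.030). Cdh1, E-cadherin, fell by 1.97 ± 0.32 (adjusted p = 0.0069), and Il1r2, the decoy receptor of interleukin-1, fell by 1.81 ± 0.13 (adjusted p = 2.5e-04). Besides Mgl2 and Clec10a, the chemokine gene Ccl22 was undetected on all MR-positive arrays and at least 1.22-fold lower (adjusted p = 0.034). Ccl8 did not pass without the MR-negative array of M2 (adjusted p = 0.061), the MR-negative array of M3 (0.072) or the MR-positive array of M3 (0.076), and leaving out either M3 array left 5 genes of the list called.

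Interferon response genes were higher in MR-positive cells, with 7 of 27 measured genes rising, 1 falling and 19 not passing, the same counts when adjusted over the list alone, and 9 rising and 2 falling with the block. The median log2 difference was 0.30 (camera adjusted p = 0.013, and adjusted p = 0.67 with an estimated correlation), and fry gave an adjusted p of 0.078. The antiviral genes Rsad2 (1.56 ± 0.14, adjusted p = 6.7e-04) and Ifit2 (1.53 ± 0.24, adjusted p = 0.0063) rose, as did Gbp2, a guanylate-binding protein (1.06 ± 0.12, adjusted p = 0.0020), and its relative Gbp3 (0.96 ± 0.17, adjusted p = 0.012, but 0.055 and 0.058 without the MR-positive array of M2 and the MR-negative array of M3). Isg20, an exonuclease, fell by 0.54 ± 0.14 (adjusted p = 0.045). With equal medians 4 interferon response genes rose and 1 fell. The list did not pass without the MR-positive array of M1 (adjusted p = 0.098, 5 genes called), the MR-negative array of M3 (0.054, 3 called) or both M1 arrays (0.075), and without the MR-positive arrays of M2 and M3 3 and 5 genes were called. Inflammatory cytokine and chemokine genes missed the threshold (median log2 difference 0.40, camera adjusted p = 0.058) and passed with the block (adjusted p = 0.018, and 0.33 with an estimated correlation). Of 21 measured, 4 rose, 0 fell and 17 did not pass by limma (9 and 2 at an unadjusted p under 0.05), with 4 and 2 when adjusted over the list alone, and with 10 and 4 with the block. Il1a, interleukin-1α, rose by 2.15 ± 0.37 (adjusted p = 0.0092), the acute phase gene Saa3 by 1.93 ± 0.36 (adjusted p = 0.012), and the chemokine genes Ccl9 and Ccl6 by 1.21 ± 0.13 (adjusted p = 0.0013) and 1.07 ± 0.14 (adjusted p = 0.0035). Saa3 did not pass without either M3 array (adjusted p = 0.055 for each). The inflammatory list passed without the MR-negative array of M1 (adjusted p = 0.012, 8 genes called), the MR-positive array of M2 (0.020) or the MR-positive array of M3 (0.027), and without both arrays of M1 (0.033), M2 (0.035) or M3 (0.047). It also passed after cyclic loess (0.049), with equal medians (0.0098), with array weights (0.047) and with a detection p under 0.01 on all 6 arrays (0.017).

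Among cell type markers, macrophage genes were higher in MR-positive cells as a list. Of 18 measured macrophage genes, 6 rose, 0 fell and 12 did not pass by limma (9 and 0 at an unadjusted p under 0.05), with 9 rising when adjusted over the list alone (median log2 difference 0.56, camera adjusted p = 0.0021, and adjusted p = 0.13 with an estimated correlation). Gas6, a ligand of TAM receptors, rose by 2.30 ± 0.16 (adjusted p = 2.6e-04), the TAM receptor gene Mertk by 2.10 ± 0.28 (adjusted p = 0.0033), Trem2, a lipid-sensing receptor, by 1.64 ± 0.17 (adjusted p = 0.0012) and the complement gene C1qc by 1.27 ± 0.28 (adjusted p = 0.026). C1qc did not pass without the MR-positive array of M1 (adjusted p = 0.0502), the MR-negative array of M2 (0.085), or the MR-negative and MR-positive arrays of M3 (0.091 and 0.094). Adgre1, the gene of the macrophage antigen F4/80, differed by -0.18 ± 0.14 (adjusted p = 0.49) and was singled out after its value was seen. Of 13 measured monocyte genes, 5 fell, 0 rose and 8 did not pass by limma (9 and 1 at an unadjusted p under 0.05), with 8 falling when adjusted over the list alone (median -0.62, camera adjusted p = 4.1e-04, and adjusted p = 0.13 with an estimated correlation). These were Ifitm6 (-1.83 ± 0.12), Plac8 (-1.26 ± 0.15), Ly6c1 (-0.77 ± 0.13), Cd177 (-0.63 ± 0.13) and Spn (-0.47 ± 0.13). With the block, 10 macrophage genes rose and 1 fell, and 2 monocyte genes rose and 9 fell. Without the MR-positive array of any title number, or without the MR-negative array of M3, 3 monocyte genes fell, and Cd177 was past the threshold under none of these (adjusted p from 0.055 to 0.091).

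Classical dendritic cell genes moved both ways, with 10 of 23 measured genes falling, 4 rising and 9 not passing, with 11 falling and 6 rising when adjusted over the list alone, and 12 falling and 8 rising with the block. The median log2 difference was -0.44, or -0.32 with undetected genes at their bound (camera adjusted p = 0.010, and adjusted p = 0.13 with an estimated correlation). Itgae and Ccr7 were among the deepest falls. Dpp4, a surface peptidase, and Kmo, a tryptophan-degrading enzyme, were undetected on all MR-positive arrays and at least 10.5-fold and 4.21-fold lower (adjusted p = 5.1e-05 and 5.5e-05). The 4 that rose were Slamf7 (1.63 ± 0.17), Itgax (1.22 ± 0.19), the gene of CD11c, Sirpa (0.59 ± 0.12) and Clec9a, which was undetected on all MR-negative arrays and at least 2.10-fold higher. The list did not pass after scaling to equal medians (adjusted p = 0.051) or without both M1 arrays (0.059). Nor did it pass over probes with a detection p under 0.01 on all 6 arrays. That filter removes genes undetected in either population, Clec9a among them, and left 14 genes, 4 falling and 3 rising (median 0.21, adjusted p = 0.69).

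Markers of other cells that the culture or the gate could hold were measured too. Neutrophil and granulocyte precursor genes were lower in MR-positive cells, with 7 of 23 measured genes falling, 0 rising and 16 not passing by limma (13 and 0 at an unadjusted p under 0.05), 11 falling when adjusted over the list alone, and 14 falling with the block (median -0.69, camera adjusted p = 3.1e-05, and adjusted p = 0.13 with an estimated correlation). Stfa2 and Stfa1, cystatin-type protease inhibitors with close paralogs that their probes may not tell apart, fell with log2 differences of -3.65 ± 0.39 (adjusted p = 0.0013) and -3.48 ± 0.35 (adjusted p = 9.6e-04). Lcn2, lipocalin 2, fell by 2.92 ± 0.12 (adjusted p = 5.1e-05), and Ms4a3, a membrane protein of granulocyte precursors, fell by 1.83 ± 0.36 (adjusted p = 0.016). Ms4a3 did not pass without the MR-positive array of M2 (adjusted p = 0.054), the MR-negative array of M3 (0.072) or the MR-positive array of M3 (0.065). A second, dimmer Ms4a3 probe differed by -1.02 ± 0.33 and did not pass (adjusted p = 0.086). T and NK cell genes were lower as a list (median -0.62, mean -1.77, camera adjusted p = 0.015, and adjusted p = 0.17 with an estimated correlation). Of 8 measured, Cd3g, Klrd1 and Cd3d fell, Cd2, undetected on all MR-negative arrays, was at least 1.95-fold higher (adjusted p = 0.0017), and 4 did not pass, with 2 rising and 6 falling when adjusted over the list alone and 2 rising and 5 falling with the block. The T and NK cell list did not pass after scaling to equal medians (adjusted p = 0.051) or with all probes kept (0.060).

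The remaining cell type lists did not pass. Of 9 measured plasmacytoid dendritic cell genes, Tlr7 (1.01 ± 0.15) and Irf7 (0.66 ± 0.15) rose and Pacsin1, whose brighter probe was undetected on all MR-positive arrays, was at least 1.82-fold lower by that probe (list adjusted p = 0.44). The dimmer Pacsin1 probe differed by 0.23 ± 0.14 and did not pass (adjusted p = 0.37). Of 5 erythroid and megakaryocyte genes, the platelet chemokine genes Pf4 (2.56 ± 0.17, adjusted p = 2.0e-04) and Ppbp (1.48 ± 0.28, adjusted p = 0.013) rose and Car2, a carbonic anhydrase detected on 2 of 3 MR-positive arrays, was at least 2.39-fold lower (adjusted p = 0.0073). That list's median was -0.10 and its mean 0.49 (camera adjusted p = 0.77, fry adjusted p = 0.0027). Of 7 mast cell and basophil genes, Hdc, histidine decarboxylase, fell by 2.86 ± 0.31 (adjusted p = 0.0014, list adjusted p = 0.68). Of 5 B cell genes, Cd22, undetected on all MR-negative arrays, was at least 1.18-fold higher and Blk, undetected on all MR-positive arrays, at least 2.73-fold lower (list median -0.02, camera direction up, adjusted p = 0.86). Of 2 measured eosinophil genes, too few for a list test, Prg2 fell by 1.03 ± 0.21 (adjusted p = 0.017) and Ear6 differed by -0.16 ± 0.41. Counts adjusted over the list alone were 3 higher and 1 lower for plasmacytoid, 2 and 1 for erythroid and megakaryocyte, 1 and 1 for mast cell and basophil, 1 and 1 for B cell and 0 and 1 for eosinophil genes. With the block, 4 plasmacytoid genes rose and 1 fell, 2 mast cell and basophil genes rose and 1 fell, and 2 B cell genes rose and 1 fell. Without the MR-negative array of M1, 5 plasmacytoid genes were called, and 2 mast cell and basophil genes were called without either M1 array. Cd22 passed with no single array left out, and Blk only without the MR-negative array of M1. Neither Cd22 nor Blk passed with normexp at offset 50 (adjusted p = 0.085 and 0.060) or cyclic loess (0.0501 and 0.061). With equal medians Cd22 (0.072) and Irf7 (0.073) did not pass. Leaving out 1 array also ended the calls of Irf7 (adjusted p 0.057 to 0.108 without the MR-positive array of M1, M2 or M3 or the MR-negative array of M3), Ppbp (0.059 without the MR-negative array of M3) and Prg2 (0.067 without the MR-positive array of M2, 0.054 without the MR-negative array of M3).

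Proliferation genes differed more between title numbers than between populations. The mean log2 intensity of the 31 measured genes was 8.01 and 7.54 on the MR-negative and MR-positive arrays of M1, against 6.16 and 5.96 for M2 and 6.63 and 6.37 for M3. Of these genes 1 fell in MR-positive cells, the centromere gene Cenpa (-0.77 ± 0.17, adjusted p = 0.027), 0 rose and 30 did not pass, and 0 passed when adjusted over the list alone by limma, where 1 gene had an unadjusted p under 0.05. The list's median log2 difference was -0.30 (camera adjusted p = 0.12), and it passed with the block (adjusted p = 2.1e-04, with 12 genes falling, and 0.57 with an estimated correlation). It also passed without the MR-positive array of M1 (adjusted p = 6.1e-04), the MR-negative array of M2 (0.0019) or the MR-negative array of M3 (0.032). Cenpa did not pass without any 1 of the M2 and M3 arrays (adjusted p from 0.076 to 0.105). It also did not pass with the mean of its probes (-0.59, adjusted p = 0.081), the dimmer one differing by -0.40 ± 0.22 (adjusted p = 0.31).

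Lists of general metabolism and stress did not pass. None of 33 oxidative phosphorylation genes (median -0.0032, camera adjusted p = 0.75) and none of 19 glycolysis and hypoxia genes (median 0.01, mean -0.01, adjusted p = 0.86) was called by limma. The 2 with the smallest p in each were Sdhb (0.30 ± 0.12, adjusted p = 0.16) and Ndufs8 (-0.37 ± 0.13, adjusted p = 0.12), and P4ha1 (0.55 ± 0.15, adjusted p = 0.051) and Ankrd37 (-0.36 ± 0.14, adjusted p = 0.14). Of 19 genes of sorting stress and immediate early response, Hspe1, a mitochondrial chaperonin, fell by 0.53 ± 0.13 (adjusted p = 0.033), and the list's median was 0.01 and its mean 0.14, with camera's direction down (adjusted p = 0.91). Of 13 cholesterol synthesis genes, Idi1, isopentenyl diphosphate isomerase, fell by 0.75 ± 0.14 (adjusted p = 0.014), and the list (median -0.15, camera adjusted p = 0.13) passed with the block, with 6 genes falling (adjusted p = 0.033, and 0.33 with an estimated correlation). Adjusted over the list alone, 1 cholesterol gene fell and 0 passed in the other 3 lists of this group, where 2 stress genes, 3 oxidative phosphorylation genes and 4 glycolysis genes had an unadjusted p under 0.05. With the block, 5 stress genes rose and 2 fell, 2 glycolysis genes rose and 2 fell, and 1 oxidative phosphorylation gene fell. Ndufs8 (adjusted p = 0.030), P4ha1 (0.010) and Ankrd37 (0.040) were among these, and Sdhb was not (0.084). Hspe1 did not pass without the MR-positive array of M1 or any 1 of the M2 and M3 arrays (adjusted p from 0.082 to 0.133), and Idi1 did not pass without the MR-positive array of M2 (adjusted p = 0.054). The cholesterol list passed without the MR-positive array of M1 (adjusted p = 0.0068), the MR-negative array of M2 (0.046) or the MR-negative array of M3 (0.041).

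**Figure D3:**
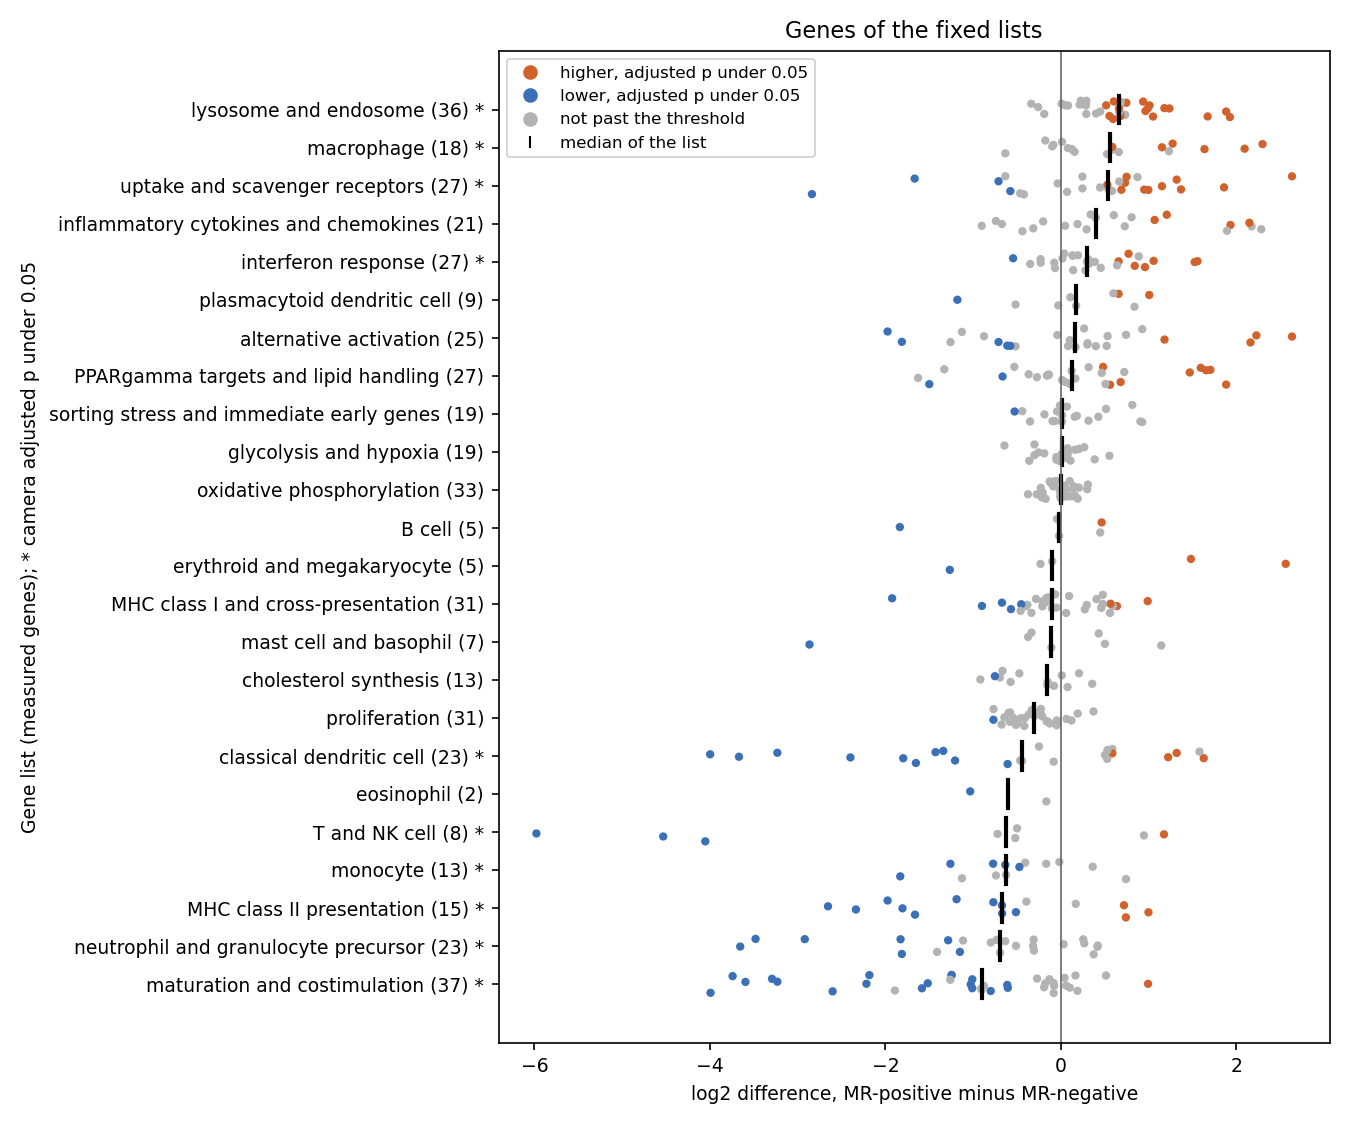
Log2 difference (MR-positive minus MR-negative) of each measured gene of the 24 lists, with orange points for genes higher and blue points for genes lower in MR-positive cells at an adjusted p under 0.05, grey points for the others, and a black bar at each list's median. Points are spread vertically only to keep them apart. Lysosomal genes lie mostly to the right (median 0.67) and maturation genes to the left (median -0.90), and the asterisk marks the 10 lists past the threshold of camera with its preset correlation, of which 0 pass with an estimated correlation (7 lists had an unadjusted p under 0.05 there).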

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

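The fits with the block but without the M1 arrays, the block joined with an estimated correlation, and the leave-outs of the detected probe count were chosen after the data were seen, and the other alternatives before. The count of 2298 probes past the threshold rose to 4628 with the title number as a block, 4944 with array weights and 3814 with the block and without the M1 arrays. It fell to 972 at an adjusted p under 0.01 and to 423 when at least a 1.5-fold difference was tested, both of which are stricter by construction. Leaving out arrays gave 219 (both M3 arrays) to 3441 (both M1 arrays), with 533 without both M2 arrays, where fewer arrays raise the standard error, while the rise without the M1 arrays came despite their loss. Other settings gave 1659 probes of 45281 with no filter, 1690 of 12139 with a detection p under 0.01 on all 6 arrays, and 2273 to 2395 with other backgrounds or scalings, the authors' values or another variance model. Equal medians turned the balance of calls to 30.6% higher, against a shift of -0.11 in the median of all tested probes. With the block each log2 difference stays the same while its standard error changes, for Mrc1 from 0.39 to 0.13. What lay behind the rises and this turn was not tested further.

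The count of 10 gene lists was 8 to 13 under the other scalings, filters, fits and leave-outs. It was 0 with an estimated correlation, with or without the block. A larger correlation between genes cannot be the cause for every list. In the unblocked fit the estimates for the lysosomal (0.0096), monocyte (-0.023) and classical dendritic cell (-0.031) lists lay under the preset 0.01, yet these lists stopped passing. With an estimated correlation camera uses the few degrees of freedom that 6 arrays leave, so the same statistic gives a larger p. The count of 0 is therefore no evidence against these lists by itself. In the unblocked fit with the estimated correlation 7 lists had an unadjusted p under 0.05, and the smallest adjusted p was 0.069. By fry 11 lists passed, and 13 by camera with the block, which added the inflammatory, proliferation and cholesterol lists. No list that had passed turned to a call in the opposite direction. The stricter filter removes genes undetected in either population. With it the classical dendritic cell list fell from 23 to 14 genes and had a positive median, without a call. Interferon response genes and classical dendritic cell genes did not pass with the block and without the M1 arrays (adjusted p = 0.057 and 0.062). Mrc1 stayed higher throughout, at 2.31 to 2.997 with arrays left out. Without both M3 arrays it did not pass (2.74, adjusted p = 0.111), where 4 arrays remained, and its adjusted p over all alternatives ran from 3.0e-05 to 0.111.

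Of the 84 named genes called, none was called in the opposite direction under any alternative. All 84 passed with the block, without background correction, with the authors' values, with the other variance model and with array weights, 80 with normexp at offset 50, 81 with cyclic loess and 80 with equal medians. When the mean of a gene's probes was used, 82 passed. With no filter 66 passed, and with the stricter filter 59 of the 60 still tested. Leaving out single arrays kept 67 to 83, and leaving out both arrays of M1, M2 and M3 kept 83, 57 and 34. The difference in detected probes per array (-390) was -80.7 at a detection p under 0.01 (exact permutation p = 0.9) and -636 to -259.5 with arrays left out, and the labels give no slide or scan, so that alternative was not run. Signal over background limits the values of genes that were undetected in one population, for which a bound is given.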

Other observations

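Tests of whether 1 cross-binding probe lies behind the T cell genes, of whether granulocytes are the whole source of the largest neutrophil gene falls, and of a difference shared by both M1 arrays were chosen after the result was seen, as were the gene families and title-number genes described first. Some ribosomal protein and semaphorin genes were lower in MR-positive cells. Among 142 families of at least 8 measured genes that share the stem of their symbol, 3 were lower and passed camera's preset test, and each of the 3 had an adjusted p of 0.75 with an estimated correlation. Of 31 genes with the stem Rpl, 11 fell, 0 rose and 20 did not pass (median -0.44, adjusted p = 9.1e-07), and of 25 with the stem Rps, 7 fell, 0 rose and 18 did not pass (median -0.41, adjusted p = 8.1e-05). At an unadjusted p under 0.05 by limma, 19 Rpl genes fell and 0 rose, 15 Rps genes fell and 1 rose, and 5 semaphorin genes fell and 0 rose. Rpl13a fell by 1.07 ± 0.11, Rpl4 fell by 1.05 ± 0.21 and Rps6 fell by 0.90 ± 0.13. The stems also catch Rpl3l, a muscle paralog, and the kinase gene Rps6ka5, both of which fell. Of the 8 semaphorin genes measured, which encode guidance and adhesion signals, 5 fell, 0 rose and 3 did not pass (median -1.19, adjusted p = 0.0013). Sema4a fell by 1.16 ± 0.15, and Sema7a, detected on 2 of 3 MR-positive arrays, was at least 7.77-fold lower, while Sema6d, Sema4f and Sema3f were undetected on all MR-positive arrays and at least 5.28-fold, 6.56-fold and 1.91-fold lower. The 3 families were lower under all 5 other backgrounds and scalings (equal medians -0.68, -0.68 and -1.29, where the median of all genes was -0.11).

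Both M1 arrays stood apart from the others in several of the fixed gene lists, a difference for which no test between title numbers was run. Against the mean of M2 and M3 in the same population, 29 of 31 proliferation genes and 12 of 13 cholesterol synthesis genes were higher on both M1 arrays. Of 19 genes of sorting stress and immediate early response, 13 were higher and 2 lower on both, with median differences of 0.84 on the MR-negative and 0.85 on the MR-positive array. Of 21 inflammatory cytokine and chemokine genes, 14 were higher and 4 lower on both. The survivin gene Birc5 was higher by 2.40 on the MR-negative and 2.37 on the MR-positive array, Top2a, a topoisomerase of dividing cells, by 2.50 and 2.26, and the replication gene Mcm5 by 2.32 and 2.14. Of the chemokine genes, Ccl2 was higher by 2.98 and 1.73, and Ccl4 by 2.38 and 1.85. The costimulatory receptor gene Tnfrsf9 was lower (-1.68 and -2.60).

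Cd3g, Cd3d and Klrd1 were lower in MR-positive cells, and T or NK cells that took up no ovalbumin would have been sorted into the MR-negative fraction. The other 15 T and NK cell markers had a median difference of -0.0077 (95% interval from order statistics over these genes, not over arrays, -0.21 to 0.099). Most of them were undetected in MR-negative cells and could not fall further, so this median does not weigh the content of such cells. That 10 of them were detected on no MR-negative array argues against such cells as the source as far as these probes respond, which was not tested. The 4 detected on all MR-negative arrays differed by far less than Cd3g (-5.98), at -0.72 for Thy1, -0.52 for Prf1, -0.50 for Cd8b1 and 0.95 for Il7r, and 0 of them passed by limma (4 at an unadjusted p under 0.05). Their calls depended on the fit. Of the 8 measured genes of the list, 2 rose and 5 fell with the block, and 2 rose and 6 fell when adjusted over the list alone. Both counts include calls among these 4. Whether a single probe that binds another transcript lies behind these falls was not decided. Of Cd3g, Cd3d and Cd6, 3 of 3 were called lower by their own probes, but they were picked for their falls, so this outcome was fixed. Cd3g and Cd3d each rest on a single tested probe. The 3 separate Cd6 probes, at -3.79, -3.92 and -4.11, argue against it for Cd6 alone. Expression by MR-negative dendritic cells themselves is a hypothesis that was not tested, and none of the 8 measured genes of the list is in another list.

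Neutrophil genes were lower in MR-positive cells, and granulocytes left in the culture could have been sorted as MR-negative. The 12 granule and surface genes had a median difference of -0.47 (95% interval -0.80 to 0.033), with S100a8 at 12.75 in MR-negative and 11.64 in MR-positive cells, which leaves granulocytes open as a source of the falls. The interval treats the 12 chosen genes as independent and measures the spread between them, not between arrays. The lower end of that interval, -0.798, fell short of the falls of Stfa1 (-3.48), Stfa2 (-3.65) and Lcn2 (-2.92). This does not decide whether granulocytes were the whole source of those falls. Several of the 12 genes lay too near the lowest detected level in MR-negative cells to fall so far, such as Cxcr2 (4.46), Camp (5.28) and Elane (5.77). Others stayed bright in MR-positive cells, such as S100a8 (11.64) and S100a9 (9.56), and whether dendritic cells express them was not tested. Of the 23 measured genes 22 were detected on all arrays and 1 is also in another list. A change in these genes within dendritic cells stays open and was not tested.

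The MR-negative array of M1 lay closer to the MR-positive arrays on the first principal component (-29.5 against -40.2 and -36.9). MR-positive cells left in that sort may account for this, but the test did not decide: of the 300 genes with the largest rise between the M2 and M3 arrays, 61.3% were higher on the M1 MR-negative array and 47% on the M1 MR-positive array, and of the 300 with the largest fall 30.3% and 57.3%. The deviations of the 2 M1 arrays correlated at 0.734 across genes, which are not independent replicates, but a difference that both populations share is left open as the account of this pattern, since the MR-positive array of M1 moved the other way on that component (34.1 against 36.1 and 36.4). What M1 stands for is not given in the sources used here, and no biological explanation was tested.

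The 6 arrays can be split into groups of 3 in 10 ways. For the probe count, 1 of the 10 splits, the real one, gave 2298 probes or more, and the highest other count was 0. Each other split puts both populations on either side, so their difference adds to the spread within a side. A low probe count was thus likely in advance there and does not weigh the count of 2298. For the gene lists it was again 1 of 10, with 10 lists against at most 7 in the others. The splits are too few for a share under 0.05. Of the 10 splits 4 part all 3 title-number pairs, and the other 3 of these gave 0 probes and 2, 3 and 5 lists, while the 6 that part 1 pair gave 0 probes and 5 to 7 lists.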
